A study of Mus musculus with 6 samples.

How the data were processed

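Small RNA was measured in pachytene spermatocytes, the germ cells in the long pachytene stage of meiosis, from mouse testes in 4 libraries: 2 from wild type (WT), 1 from Alkbh1-/- and 1 from mice homozygous for a Tzfp gene trap (TzfpGTi/GTi). mRNA was measured in 1 WT and 1 Alkbh1-/- library. Per the labels' protocols, the Alkbh1 line lacks exon 6, and the gene trap brings a splice acceptor upstream of exon 1 of Tzfp. RNA under 200 nt entered a small RNA kit (50 ng, 15 PCR cycles) and was read as 36 bp single ends. Larger RNA was selected with oligo(dT), from 1 µg of WT and 1.6 µg of Alkbh1-/- RNA, and read as 75 bp paired ends. No label says which animals the WT libraries came from, so p-values measure the spread between these libraries, which may be technical.

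The deposited small RNA tables give, for each cluster, its mm9 position, a name and an expected count: the authors' values need not be whole. All of the 14343 values under 100 were multiples of 1/60, within 0.01 of a sixtieth, as when reads with several positions are divided among them. Novoalign, TopHat, bedtools, CASAVA 1.3 and mm9 are named in the submitters' processing notes, without their roles. Clusters have either a number (2260) or a name beginning piC (2684); what separates these classes is not given in the sources used here. In total 4944 clusters had reads in any library and 3408 in all 4, and 277 overlapped a cluster with more reads. The deposited mRNA table holds whole-number read counts per Ensembl gene; the counting tool's settings and strand use are not given in the sources used here. Of its 21310 gene identifiers, 19848 (93.1%) matched a symbol. Identifiers of the 13 mitochondrially encoded genes, of Sycp3 and of several other list members were not matched, so these were not analysed here.

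The expected counts were rounded to whole numbers. Clusters with a summed deposited value of 40 or more over the 4 libraries were kept (2209, holding at least 99.9% of reads in each library). edgeR 4.0.16 in R 4.3.3 fitted 1 coefficient per genotype with TMM scaling, and its quasi-likelihood test was adjusted by Benjamini-Hochberg at a threshold of 0.05. Each mutant had 1 library, so the fit had 1 residual degree of freedom, from the WT pair. Each mutant library was assumed to vary like WT (biological coefficient of variation 0.257). The fit also drew on the spread across clusters (median prior degrees of freedom 6.81), so a cluster's p-value does not rest on its own WT pair alone. Standard errors (SE) were taken from the fold and the F statistic. The test and the list percentile were tested on simulated data. With 200 clusters changed, the test over 2211 clusters of the Alkbh1 comparison recovered 61.4% of 4-fold, 94.1% of 16-fold and 98.5% of 64-fold changes, and 4 of its 167 calls were false. For the Tzfp comparison over 2190 clusters these were 67.9%, 100% and 100%, with 11 false calls of 175. The simulated mutant libraries had the same spread as WT, so these rates do not hold if a real mutant library varies more. The rates also apply only with 200 changed clusters. Where few clusters change, the adjustment is stricter and fewer changes of the same fold would pass.

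For mRNA, counts were scaled by TMM to CPM, counts relative to the library total, and log2((Alkbh1-/- + 1)/(WT + 1)) was taken, with a pseudocount of 1 CPM that understates the change of low genes. Genes with 5 CPM or more in at least 1 library were counted at 2-fold. With 1 library per genotype there was no test. Intervals on ratios are exact (Clopper-Pearson, 95%), and shares of reads have 95% Wilson intervals. Both cover counting error only, since PCR copies without molecular identifiers are not independent molecules. The median of each gene list, over members with 1 CPM or more, was placed among 10000 random lists matched on mean expression. Of 100 random lists of 20 genes among the 15865 measured, 4 fell outside the central 95%, and all 100 did after a shift of 0.5 on the log2 scale. Genes of a real list can vary together, so this does not give how often real lists fall outside. Gene lists covered the AlkB family, the piRNA pathway, stages of spermatogenesis, somatic cells of the testis, stress, chromatin, DNA repair and housekeeping groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and DESeq2 1.42.0 were also used. Gene names and chromosomes came from tables on GRCm38, whose coordinates were not used.

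Groups, tests, lists and the rule for named items were set before the data were examined. The rule named up to 12 clusters per direction that passed the threshold and lay outside both WT libraries. Where fewer than 5 passed, it named those with a mean of 20 or more counts whose distance from the nearer WT library exceeded the WT difference. It also named the 10 clusters with most WT reads and 1082B, the cluster the study is named for, which the study chose on these samples. For mRNA it named Alkbh1 and Zbtb32 (Tzfp), the 12 highest and 12 lowest genes, and members of the lists at 2-fold. 1082B is called the study cluster in the results. Its neighbours on one side, 1082A (near) and 1081 (far), and 1082C on the other (the opposite neighbour), were set beside it after their values were seen. Alternatives were DESeq2 size factors, no scaling beyond totals, the DESeq2 Wald test, other count filters, fits with only 1 mutant, each WT library left out, overlapping clusters counted once, other pseudocounts and floors, and median centring. Before the exact form of the filter was settled, 3 closely related fits had been run and their calls seen; the form kept reads the filter on the deposited sums, as worded beforehand, and calls the fewest of the 3, and the other forms are reported as alternatives chosen after seeing the data.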

Results

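In small RNA libraries from mouse pachytene spermatocytes, the counts of piRNA clusters, the genomic regions from which PIWI-bound small RNAs are made, summed to 10193940 (WT replicate 1), 15319520 (WT replicate 2), 7306115 (Alkbh1-/-) and 14760893 (TzfpGTi/GTi). Reads in overlapping clusters can enter these sums more than once, and so the shares of reads below. Without the clusters that overlap one with more reads, the sums were 9697025, 14570998, 6920789 and 14040209. The mRNA libraries held 8222671 counts in WT and 10229260 in Alkbh1-/-. Alkbh1 is a member of the AlkB dioxygenase family and Tzfp (Zbtb32) is a BTB zinc finger protein. The study's title names both as repressors of a piRNA cluster outside repeats. The names of the deposited tables follow one scheme for WT replicate 1 and Alkbh1-/- and another for WT replicate 2 and Tzfp; no label gives a batch, so folds of the called clusters and of the study cluster are also given against each WT library.

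The WT libraries set the replicate error. Of the 2209 clusters tested, 75.3% lay within 1.5-fold and 90.3% within 2-fold of each other in the WT pair, with an SD of 0.60 for the log2 ratio and a Pearson correlation of 0.974 across clusters, which are not independent replicates. Their counts differed by more than counting noise (chi-square of 33.8 per degree of freedom), which does not tell technical from biological spread. For Alkbh1-/- the SD of the log2 ratio was 0.714 to WT replicate 1 and 0.812 to replicate 2, and for Tzfp 0.593 and 0.524. By SD each mutant lay nearer the WT library that shares its naming scheme. Chi-square per degree of freedom gave the same order for Alkbh1-/- (127 and 205) but not for Tzfp (39.2 and 46.4). The fit had no term for the scheme, and whether it marks a batch was not tested. The 10 most abundant WT clusters held 49.6% of reads (95% Wilson interval 49.5 to 49.6) in WT replicate 1, 48.5% (48.5 to 48.6) in replicate 2, 49.3% (49.3 to 49.4) in Alkbh1-/- and 48.8% (48.8 to 48.8) in Tzfp. Cluster 2249 on chromosome 17 was the most abundant, with 8.44% of reads (8.42 to 8.45) in WT replicate 1 and 8.08% (8.07 to 8.10) in replicate 2. It held 12.7% (12.7 to 12.7) in Alkbh1-/- and 8.97% (8.95 to 8.98) in Tzfp. Its log2 fold was 0.50 ± 0.25 (SE) in Alkbh1-/- (adjusted p = 0.431, edgeR). Of the 10 most abundant clusters, 8 had a log2 fold below 0 in Alkbh1-/- (median -0.28, lowest -0.47). Numbered clusters held between 93.0% and 93.4% of reads in every library.

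The comparison of Tzfp with WT asked which clusters depend on Tzfp. The cluster the study is named for (mm9 chromosome 7, 132472368 to 132476593) rose in the Tzfp library, and the nearer of the clusters on its left, called the near neighbour here (132448301 to 132458800), fell. The study cluster had 4 reads in WT replicate 1, 94 in WT replicate 2, 1858 in Alkbh1-/- and 57188 in Tzfp. These were 3.92e-05% (1.53e-05 to 0.000101), 0.000614% (0.000501 to 0.000751), 0.0254% (0.0243 to 0.0266) and 0.387% (0.384 to 0.391) of cluster reads. The log2 fold of Tzfp over WT was 10.06 ± 1.14 (SE; 1 mutant and 2 WT libraries; edgeR quasi-likelihood adjusted p = 0.0322). It was 13.34 against WT replicate 1 and 9.18 against replicate 2, a 580-fold difference from the nearer library.

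The near neighbour, whose end lies 13567 bp from the study cluster, had 257.5 and 383 reads in WT, 199 in Alkbh1-/- and 34 in Tzfp, a log2 fold of -3.47 ± 0.40 in Tzfp (adjusted p = 0.0322). It was 10.5-fold lower than in WT replicate 1 and 11.8-fold lower than in replicate 2. A far neighbour on the same side lies 100 bp beyond it and had 36 and 69 reads in WT, 15 in Alkbh1-/- and 4 in Tzfp. Its log2 fold of -3.89 ± 0.63 did not pass (adjusted p = 0.213), but passed without the count filter (5.52e-05), and its adjusted p reached 0.996 with no scaling. On the other side, the opposite neighbour (132493001 to 132509300) had a log2 fold of 0.46 ± 0.36 in Tzfp (adjusted p = 1.00). Among all 2209 clusters, the study cluster ranked 1 from the top in Tzfp, while the far and near neighbours ranked 1 and 2 from the bottom. The study chose its cluster on these samples, so the rank and p-value of that cluster are not independent of the choice. The neighbours were set beside it after their values were seen.

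**Figure D1:**
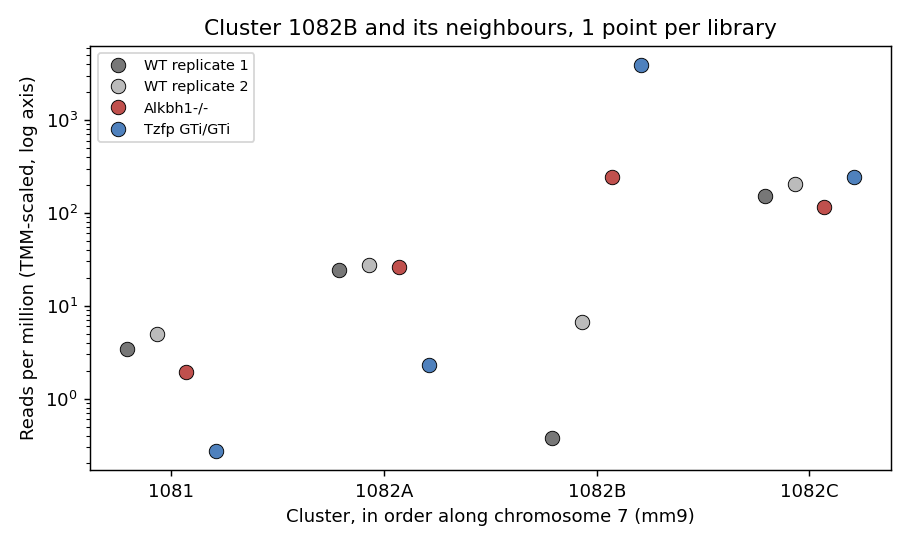
TMM-scaled CPM on a log axis for the far and near neighbours, the study cluster and the opposite neighbour, in their order on mm9 chromosome 7, with 1 point per library and no error bars. In the study cluster the Tzfp library stands at 3899 and Alkbh1-/- at 241, against 0.376 and 6.72 in WT, while the Tzfp library is lowest in the far and near neighbours.

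Apart from the study cluster and its near neighbour, no cluster passed in Tzfp, and 41 had an unadjusted p under 0.05 (8 by DESeq2's Wald test, which also called 2). These 41 are fewer than the share of 0.05 of the 2209 that unchanged clusters would give in a well-calibrated test. The WT libraries differed more from each other (SD of the log2 ratio 0.604) than Tzfp did from WT replicate 1 (0.593) or replicate 2 (0.524). A lack of calls in Tzfp is thus not a lack of change. Further clusters named by the rule had smaller folds and did not pass. The highest were piC_1349 on chromosome 17 (log2 fold 1.98 ± 0.53), piC_551 on chromosome 7 (1.46 ± 0.53) and 1999 on chromosome 14 (1.38 ± 0.44). The lowest were piC_1267 on chromosome 15 (-1.57 ± 0.60) and piC_389 on chromosome 5 (-1.30 ± 0.58). All 10 of the most abundant clusters lay between -0.11 and 0.09. The 15 clusters of the X chromosome had a median log2 fold of 0.25 in Tzfp, at the 98.6th percentile of matched random lists. Their share of reads in Tzfp, 0.0300% (0.0291 to 0.0309), lay between those of the WT libraries, 0.0463% (0.0450 to 0.0477) and 0.0205% (0.0198 to 0.0212), and it was 0.0701% (0.0682 to 0.0721) in Alkbh1-/-. The calls of the study cluster and the near neighbour were both lost when overlapping clusters were counted once (adjusted p = 0.235 and 0.139), with no scaling beyond totals (0.996 and 0.785) or with a floor of 200 counts (0.172 and 0.0682). In these fits the log2 fold stayed above 10 for the study cluster and between -3.47 and -3.44 for the near neighbour; both calls held in the other 6 settings that gave a test.

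The comparison of Alkbh1-/- with WT asked the same of Alkbh1. Of 2209 clusters, 6 rose and 0 fell. Cluster 1999 (chromosome 14, 95950701 to 95976300) had 22.7 and 16.5 reads in WT and 330 in Alkbh1-/-, a log2 fold of 4.71 ± 0.41 (SE; adjusted p = 0.00802). Cluster 70 (chromosome 1, 56823401 to 56843600) had a log2 fold of 3.30 ± 0.44. On chromosome 17, piC_1397 (39979942 to 39985771) and the overlapping piC_2849 shared nearly all their reads, 18280 in Alkbh1-/- against 4586 and 3264 in WT, with a log2 fold of 2.83 ± 0.40. Whether these reads are piRNA was not tested, since read lengths and an mm9 annotation were not used here. The others were piC_1464 on chromosome 19 (2.38 ± 0.33) and piC_2196 on chromosome 8 (2.25 ± 0.31), each with adjusted p = 0.0466. Each of the 6 exceeded both WT libraries. Over WT replicates 1 and 2, cluster 1999 was 20.1-fold and 36.3-fold higher, cluster 70 was 7.41-fold and 14.6-fold higher, and piC_1397 and piC_2849 were each 5.49-fold and 10.15-fold higher. The same folds were 4.61 and 5.95 for piC_1464 and 4.64 and 4.87 for piC_2196.

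The study cluster had the highest log2 fold in Alkbh1-/- too, 6.04 ± 1.00, and missed the threshold (adjusted p = 0.0614). It was 640-fold above WT replicate 1 and 35.8-fold above WT replicate 2, and the WT libraries themselves differed 17.8-fold in this cluster. The near neighbour had a log2 fold of -0.0027 ± 0.32 (adjusted p = 0.998), and the far neighbour had -1.10 ± 0.50 (adjusted p = 0.411). The opposite neighbour had -0.63 ± 0.37. The number of calls moved between 0 and 41 with the processing, and clusters also fell in some settings: 13 rose and 1 fell under DESeq2 size factors, 19 and 5 by DESeq2's Wald test, and 34 and 7 without the filter. In the main setting 283 clusters had an unadjusted p under 0.05 (109 by DESeq2's Wald test), so the list of 6 is uncertain. The study cluster passed in Alkbh1-/- under DESeq2 size factors (adjusted p = 0.0400), without the filter (1.80e-20) and with unrounded totals and another library order (0.0495). It did not by DESeq2's Wald test (0.106), with overlaps counted once (0.172), with only WT and the mutant (0.182), with no scaling (0.315), with a floor of 200 counts (0.0684) or with the filter on rounded sums (0.0583).

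Between the mutants, 0 clusters passed in the edgeR fit, with 187 at an unadjusted p under 0.05 and 15 calls by DESeq2's Wald test. The study cluster was 16.2-fold higher in Tzfp than in Alkbh1-/-, a log2 difference of -4.02 ± 1.20 for Alkbh1-/- over Tzfp (adjusted p = 0.401). No cluster was called in both comparisons with WT, and 1 was under DESeq2 size factors, without the filter, or with unrounded totals and another library order together. Independent lists of the sizes of the higher calls alone would share 0.00272 clusters, so an overlap of 0 says nothing about shared clusters. Fold changes of the mutants correlated across clusters (Pearson 0.312). For comparison, all libraries, WT included, were simulated from the mean WT rate without any change, and the simulated mutants shared the simulated WT pair. These gave a median correlation of 0.303 and up to 0.346 in 100 simulations. The covariance was 0.133 against 0.108 simulated. With a separate WT library for each mutant the correlation was 0.219 for Alkbh1-/- over WT replicate 1 and Tzfp over replicate 2, the pairs that share a naming scheme, and -0.065 with the controls crossed, with covariances of 0.0819 and -0.0314. The observed correlation lay near the simulated median and below the highest simulated value. Shared controls alone can thus give a correlation of this size, and it is no evidence of a change shared by the mutants. The value with separate controls depended on which WT library each mutant was set against.

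The mRNA comparison asked which transcripts differ in Alkbh1-/- spermatocytes. Alkbh1 itself had 21.0 CPM in WT and 20.2 CPM in Alkbh1-/- (ratio 0.962, interval 0.782 to 1.18). A count over the whole gene does not test a deletion of exon 6, so it does not check the label. Zbtb32, the gene of Tzfp, had 328 CPM in WT and 423 in Alkbh1-/- (ratio 1.29, interval 1.23 to 1.35). Of 12189 genes over the floor, 219 were at least 2-fold higher in Alkbh1-/- and 330 lower, and 83.2% lay within 1.5-fold. These folds have no replicate check.

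The highest genes at a pseudocount of 1 were Gm7853, with 0 counts in WT and 138 in Alkbh1-/- (at least 36.2-fold higher with WT at a floor of 3 counts, or 29.0-fold at the lower end of the exact interval), Ptpro, a receptor tyrosine phosphatase (30.3-fold, interval 11.6 to 113), and Zfp990 (23.3-fold, 10.5 to 64.5). Gm7853 is a predicted gene and Zfp990 a member of a zinc finger family with similar copies, so reads may be shared and their counts are uncertain. Lpo, lactoperoxidase, had 0 counts in WT and 82 in Alkbh1-/- (at least 21.5-fold higher at the same floor, or 17.1-fold by the interval). Vav2, a guanine nucleotide exchange factor, was 5.61-fold higher (4.88 to 6.48) at 1611 counts, and Afm, which encodes afamin, 4.71-fold (3.48 to 6.48). Snhg11, 1700049E15Rik, Gm5570, Tpte, Mas1 and Sez6l followed, with log2 folds from 1.77 (Sez6l) to 1.92 (Snhg11). The lowest at the pseudocount of 1 was Pla2g4a, a cytosolic phospholipase, at 65 counts in WT and 9 in Alkbh1-/- (log2 -2.26). Serpina3a (-1.79), Trpv1 (-1.78), Gm3880 (-1.77), Etd (-1.75), Frmpd1 (-1.74), Chst10 (-1.74), Defb45 (-1.74), Sox9 (-1.73), Ppp1r3c (-1.71), Snx33 (-1.71) and Sfxn3 (-1.69) followed. With a pseudocount of 5 the order of these named genes moved, with Vav2 (2.29) above Zfp990 (1.95), Gm7853 (1.88) and Ptpro (1.86), and with Serpina3a (-1.55), Sox9 (-1.50) and Snx33 (-1.45) below Pla2g4a (-1.15).

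Sertoli cell genes were the group furthest from 0. Of 18 measured members, 17 were at least 1.5-fold lower in Alkbh1-/- and 0 higher, with a median log2 fold of -1.12 (below all matched random lists). They included Sox9, the Sertoli transcription factor (3.50-fold lower, interval 2.88 to 4.28), Aard (log2 -1.39), Gata4 (-1.32) and Inhbb, an inhibin subunit (-1.31). Kitl, which Sertoli cells also make, was lower too (-1.30). Leydig cell genes lay on the other side, with 7 of 11 at least 1.5-fold higher, 1 lower and a median of 0.71 (99.99th percentile). Hsd3b6 (1.28), Scp2 (1.17) and the steroid enzyme Cyp17a1 (1.11) were higher and Nr5a1 (-1.12), which the Sertoli list also holds, was lower.

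Several germ cell lists were higher in Alkbh1-/-. With 1 library per genotype, the preparation and the genotype cannot be told apart here. Of 26 spermatid genes, 13 were at least 1.5-fold higher and 0 at least 1.5-fold lower (median 0.56, above all random lists). Catsper3, a sperm calcium channel subunit (1.23), and Sun5 (1.05) led that list. Of 30 meiotic prophase genes, 9 were at least 1.5-fold higher and 0 at least 1.5-fold lower (median 0.26, above all random lists). Prdm9 (1.39), Mnd1 (1.18) and the recombinase Dmc1 (1.00), genes of early recombination, led that list at low counts. In the piRNA pathway 3 of 24 were at least 1.5-fold higher and 0 at least 1.5-fold lower (median 0.12, 99.96th percentile). Its most expressed members Tdrd6 (-0.21) and Piwil1 (0.08) differed little. Late pachytene and division genes lay within the random range (median -0.0035), with Ldhc at -0.22 and Ybx2 at 0.0026. In spermatogonial genes, 4 of 18 were at least 1.5-fold higher and 2 at least 1.5-fold lower (median 0.22), with Kit at 1.02 and Kitl at -1.30. With a floor of 20 CPM, however, the median of the spermatogonial list was -0.39 (1.80th percentile).

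**Figure D2:**
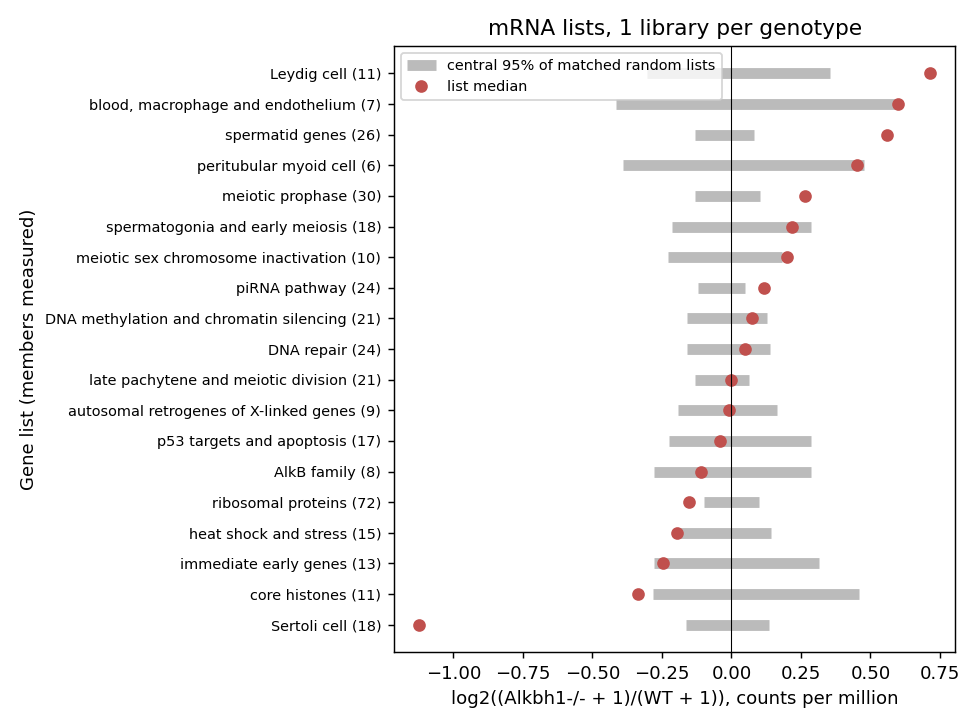
Median log2((Alkbh1-/- + 1)/(WT + 1)) of each gene list, in CPM, as points, with the central 95% of matched random lists as bars; members measured stand in parentheses and each genotype has 1 library. The Sertoli list stands at -1.12 and the Leydig list at 0.71, both outside their bars.

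Among the other lists, ribosomal proteins (median -0.15, 0.14th percentile), histone genes (-0.34, 1.43) and heat shock genes (-0.20, 1.89) had medians below the random range, with Hspb1 at -1.61. Of 34 histone genes in the table of counts, 11 were measured. By sign alone, 6 of the 11 were lower and 5 higher, while at 1.5-fold 3 were lower and 1 higher. The libraries were selected with oligo(dT), so the list speaks only for histone RNA that this selection kept. The measured histone genes included the linker histone Hist1h1c (-1.17), which the list's name pattern also takes, and Hist3h2ba, with 0 counts in WT and 13 in Alkbh1-/-. Genes of meiotic sex chromosome inactivation had a median of 0.20 (98.2nd percentile) and included Atr (-0.12) and Mdc1 (0.17). Blood and endothelial genes had 0.60 (97.7), with 4 of 7 higher and 3 lower. Within the random range were the AlkB family (-0.11), peritubular myoid cells (0.45), p53 targets (-0.041), immediate early genes (-0.24), retrogenes of X-linked genes (-0.010), DNA methylation and silencing (0.075) and DNA repair (0.049). In all, 10 of 19 lists lay outside the central 95%, where 0.95 would if their members were random genes. Members of a real list can vary together, and some belong to another list too. So 0.95 is not the number expected without a genotype effect. The positions of the ribosomal, histone, heat shock, sex chromosome inactivation and blood lists were lost under at least 1 other pseudocount or floor. Peritubular myoid genes (99.2nd percentile with no floor) and DNA repair genes (98.1st with a floor of 20 CPM) moved outside the random range, as spermatogonial genes did.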

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

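No paired analysis was possible because the labels number only the WT small RNA libraries and each mutant has 1 library. Leaving out a WT library leaves no residual degrees of freedom, so it gives folds without calls: the study cluster then ranged from 5.16 to 9.32 in Alkbh1-/- and from 9.18 to 13.34 in Tzfp. Calls in Alkbh1-/- were 6, all higher, and 14 with DESeq2 size factors (1 lower), 24 with DESeq2's Wald test (5 lower; it left 1542 adjusted p-values missing), 41 without the filter (7 lower), 2 with a floor of 200 counts, and 0 with no scaling beyond totals, with only the WT libraries and the mutant, or with overlapping clusters counted once. With no scaling the median log2 fold of all clusters in Alkbh1-/- moved from 0.0038 to 0.11. Under 2 further forms of the main fit, chosen after seeing the data, they were 10 (filter on rounded sums) and 12 (unrounded totals, another library order). The study cluster passed in Alkbh1-/- under DESeq2 size factors (6.01), without the filter (5.89) and with unrounded totals (6.04); its adjusted p there was 0.0495 and reached 0.315 with no scaling. The 2 calls in Tzfp became 0 with no scaling, a floor of 200 counts or overlaps counted once, where the study cluster stood at 10.14, 10.11 and 10.11, and 3 without the filter, where the far neighbour also passed. Calls between the mutants were 15 with the Wald test and 33 without the filter. The overlap was 1 cluster with DESeq2 size factors, without the filter and with unrounded totals in another library order, 2 choices changed together. The log2 fold of the near neighbour in Alkbh1-/-, near 0, turned to 0.11 with no scaling, 0.051 with a floor of 200, 0.032 with only the mutant and WT, 0.0041 on rounded sums, 0.048 with overlaps counted once and between -0.084 and 0.092 when each WT library was left out. In mRNA, 219 genes higher, 330 lower and 549 in all became 50, 135 and 185 with a pseudocount of 5, and 80, 200 and 280 with a floor of 20 CPM; 357 were higher with no floor. The spermatogonial median of 0.22 turned to -0.39 with a floor of 20 CPM. For every change of call the cause was not tested. Filter and floor settings change which clusters or genes are counted, but this alone does not account for the fit without the filter. There the study cluster in Alkbh1-/- had nearly its main log2 fold (5.89 against 6.04). Its adjusted p fell below even the unadjusted p of the main fit. The very small p-values of that fit rest on 1 mutant library and are not stronger evidence. The Alkbh1-/- library, with the lowest sum of cluster counts (7306115, or 6920789 without overlapping clusters), limits low clusters most.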

Other observations

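Tests of the second Sertoli list and of the spread between libraries were set before their results were seen; the others were chosen afterwards. The 94 reads of the study cluster in WT replicate 2 equal 0.164% of the 57188 reads of the Tzfp library. In the Tzfp library 14 clusters stood 2-fold above both WT libraries and 29 stood 2-fold below both, against 117 and 107 in Alkbh1-/-.

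The far and near neighbours of the study cluster were the lowest of all clusters in the Tzfp library, beside the highest, the study cluster itself. The depth taken by the study cluster shifts other clusters by -0.0056 on the log2 scale, far less than the fold of the near neighbour. The other 24 clusters within 5 Mb had a median absolute log2 fold of 0.211, under the 75th percentile of 0.486 for all others, which argues against a change across the region. Chromosome 7, which also carries Zbtb32, ranked 1 of 19 by the share of clusters beyond 2-fold in Tzfp, so a segment of another strain carried with the gene trap may contribute, but that share, 8.84%, was also 8.84% in the WT pair (rank 13) and 14.9% in Alkbh1-/- (rank 11). The 20 Mb window of the study cluster, tested first, had 6.90% against 7.29% in the median window of chromosome 7, while the next (140 to 160 Mb) had 26.3%, 5 of 19 clusters and the highest of 83 windows, and the other 6 windows of the chromosome had 3.57% to 9.52%; the strain is not given, so a local effect of Tzfp and strain cannot be told apart.

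The clusters that rose in Alkbh1-/- had a log2 fold of at least 2.22 under 3 scalings, but 1 factor per library moves all clusters alike, so this decides nothing about the scaling. Without scaling none of them passed (adjusted p = 0.298), and why the test lost them was not tested. The library itself may stand apart: WT replicate 1 stood 2-fold above WT replicate 2 and Tzfp in 72 clusters, WT replicate 2 above WT replicate 1 and Tzfp in 9, and Tzfp above both WT in 14, against 117 for Alkbh1-/- over WT (85 and 124 with Tzfp in place of a WT library), so 1 of the others came near and the spread between libraries cannot be told apart. Of Alkbh1-/- reads, 0.2502% lay in piC_1397, which may hold fragments of another RNA class such as ribosomal RNA; read lengths and an mm9 annotation were not used here, so this cannot be told apart from piRNA. An effect of the Alkbh1 genotype stays open, with 1 library.

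Lower Sertoli genes in the Alkbh1-/- mRNA library may come from less Sertoli cell RNA in that preparation, which the labels name only as pachytene spermatocytes. A second list of 16 Sertoli genes, 14 measured and none in the first list, had a median log2 fold of -0.47 (0.01th percentile, and -0.97 with a floor of 20 CPM). Of the 14 measured, 6 were at least 1.5-fold lower and 0 at least 1.5-fold higher. A loss of all somatic cells goes against the Leydig list, whose median was 0.71. Summed over the first list, Sertoli genes had 3699 CPM in WT and 1784 in Alkbh1-/-. Whether the preparation or the genotype lowered them cannot be decided from 1 library each.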
